A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

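RNA was measured in 12 samples of budding yeast in log-phase growth, in 4 groups of 3 samples. The labels describe 1 haploid MATa strain in which a tetracycline-repressible promoter drives RAP1, grown without doxycycline (control) or with 0.01, 0.1 or 0.5 µg/mL doxycycline. Per the labels' protocols, total RNA was extracted with a column kit, the molecule was polyA RNA and barcoded TruSeq libraries were made. Groups were taken from the sample labels. The labels do not say whether the 3 samples of a group came from separate cultures, so any adjusted p from them measures the spread between these samples, which may be technical.

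Per the submitters' processing notes, FastQC, Bowtie2 and Cuffdiff were used with genome build R64; versions, settings, strand handling and the annotation are not given in the sources used here. The authors' deposited tables are 3, each setting the control against 1 dose. Per the file headers, each table gives for every gene 1 level in the control and 1 level in the doxycycline group, the log2 fold change and a q-value. The headers name the control WT while the title lines say Control, and it was taken to be the control group of the labels. The headers do not state the unit of the deposited levels; FPKM (fragments per kilobase of transcript and per unit of sequencing depth) was inferred from the column names, which are those of Cuffdiff. The FPKM values were made by the authors with Cuffdiff, per the submitters' processing notes, and pool the samples of a group. Each level is the authors' pooled level of 3 samples, so no SD is given with it. The log2 fold changes were made by the authors as dose over control without a pseudocount, which was checked against the levels. The q-values, p-values adjusted by the authors for multiple tests, are used as deposited; p-values before adjustment were not used here.

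The median ratio of the control column of the 0.1 µg/mL table to that of the 0.01 µg/mL table was 0.997, and for the 0.5 µg/mL table it was 0.996. The tables were thus scaled separately, and no p-value is given for a difference between doses. Differences between tables in the closing section are described by medians over genes, a bootstrap over genes and counts of members. The depth of the libraries is unknown and no counting interval or detection floor is given. Each table holds 5085 genes, all with a gene symbol; 3 lines of each table were emptied for this work and are not analysed here. Symbols that a spreadsheet had turned into dates (2 genes) were restored from the gene identifiers. Genes at a level of 0 in either group or at a q of 1 were treated as not tested, which left 5049 genes at 0.01, 5054 at 0.1 and 5047 at 0.5 µg/mL. A level of 0 is described as listed at 0.

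A gene was called changed at a dose where the authors' q was below 0.05. This was the design set before the data were examined for tables that hold only the authors' comparisons. No test per gene was added, since the levels are pooled over samples. For the same reason samples could not be left out in turn, regrouped or compared with each other, and no count adjusted over the list alone is given.

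Before the data were examined, 31 gene lists were fixed, of which 29 are by symbol and 2 by position or sequence. After the data were seen, 2 genes that a name pattern had taken by mistake were removed: RPP1, an RNase P subunit, from the ribosomal protein list and COS111 from the COS list. For each list and dose, the share of members called higher, and of those called lower, was compared with the share among the other tested genes by a two-sided Fisher's exact test (186 tests, Benjamini-Hochberg adjusted). The list's median log2 fold change was set against 10000 random lists of the same size matched on the decile of the mean level (93 tests, Benjamini-Hochberg adjusted), which permutes genes within deciles and is printed as a permutation p; the smallest two-sided p these can give is 0.0002, which is 0.000664 after adjustment. Random lists were drawn from all tested genes and can hold ribosomal protein genes, so those matched to abundant lists can have a lower median. Under each alternative the p-values were adjusted over all lists and doses in the same way. Genes of a list are regulated together, so that these p-values describe the lists in these tables and are smaller than they would be for independent genes.

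Coordinates, coding lengths and upstream sequences came from the R64 reference assembly, in which 5017 of the 5085 genes were found by identifier. The Rap1 consensus ACACCCRYACAYM was searched on both strands within 600 bp upstream of the start codon, with at most 1 mismatch. Ribosomal protein genes with and without it were compared by the difference of median log2 fold changes, with a two-sided permutation test of 100000 resamples and adjustment over 3 doses. After the data were seen, the shares that fell were also compared, by two-sided Fisher's exact tests adjusted over 3 doses at each motif setting. Genes near chromosome ends start within 20 kb of an end. A near-identical copy is another coding sequence with at least 95% identity over at least 80% of the length by blastn 2.17.0; 150 genes have one, and their levels are uncertain because reads can be split between copies. How reads of overlapping genes on opposite strands were assigned is not given in the sources used here.

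The named genes follow a rule set before the data were examined. It takes RAP1, the 10 called genes with the largest rise and the 10 with the largest fall at each dose among those at 5 FPKM or more in the higher group, and up to 4 called members of each list. For the lists of ribosomal proteins, glycolysis, silent mating loci, regulators of ribosomal protein genes and telomere factors it allows any member. Genes named outside the rule are said to be so.

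The 3 comparisons share the same control libraries. Correlations and overlaps between doses are therefore printed beside 100 simulations of unchanged groups against a shared control. The simulation treats the whole spread of the 0.01 µg/mL fold changes as chance, so its covariance is an upper bound if the control and doxycycline groups vary alike.

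The list test was checked on simulated lists of 20 genes drawn from the real fold changes, shuffled within level deciles. Shuffled lists are random by construction. The share of them passing without a shift was thus set in advance and says nothing about genes regulated together. With no shift, 3 of 60 lists at 0.01 (5049 genes), 1 of 60 at 0.1 (5054 genes) and 3 of 60 at 0.5 µg/mL (5047 genes) had an unadjusted p below 0.05. With a shift of 0.3 on the log2 scale, 52, 43 and 35 of the 60 lists at these doses did, and with a shift of 1 all 60 did at each dose. The alternatives tried were a q below 0.01, a minimum change of 2-fold, a minimum mean level of 1 FPKM, centring of the fold changes on the median of all genes or of the genes outside 4 lists, log2 of the level plus 1, members at 10 FPKM or more, other motif and distance settings, and others chosen after the data were seen. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.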

Results

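Budding yeast cells in which a tetracycline-repressible promoter drives RAP1 were profiled by RNA sequencing in log phase. Rap1 is an essential DNA-binding protein that activates ribosomal protein and glycolytic genes and takes part in silencing at telomeres and the silent mating loci. In the tet-off system a tetracycline-controlled activator drives the promoter, and doxycycline releases it. The control group and the groups labelled 0.01, 0.1 and 0.5 µg/mL doxycycline had 3 samples each, 12 in all. The comparisons ask how the transcriptome changes as RAP1 expression is lowered in steps. Levels below are the authors' pooled FPKM of a group and calls rest on the authors' q below 0.05, both from the authors' deposited tables, so no SD is given and the depth is unknown.

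RAP1 mRNA (YNL216W, chromosome XIV, 241689 to 244172 in R64) fell at 0.5 µg/mL and was not called at the lower doses. In the authors' deposited table for 0.5 µg/mL its level was 22.0 FPKM against 31.5 FPKM in the control, a log2 fold change of -0.52 (q = 0.00764). At 0.01 µg/mL it was, in the authors' deposited table, 33.3 FPKM against 31.7 FPKM (log2 fold change 0.07, q = 0.827). Its level at 0.1 µg/mL in the authors' deposited table was 31.0 FPKM against 31.5 FPKM (log2 fold change -0.02, q = 0.935). A decrease of RAP1 mRNA was thus not detected in the groups labelled 0.01 and 0.1 µg/mL, and Rap1 protein was not analysed here. The design describes lowered RAP1 with doxycycline, which RAP1 mRNA did not show in these 2 groups, and an exchange of labels could not be checked from pooled levels. Doses below are therefore those of the labels. The median log2 fold change of all tested genes at 0.5 µg/mL was itself -0.30, and relative to it RAP1 stood at -0.22. RAP1 lay between the lower and upper quartiles of all tested genes at that dose (-0.64 and 0.02). Of 5047 tested genes, 1962 were called lower there. The fall of RAP1 mRNA was thus not set apart from the shift of all genes. Genes of the strain's genotype, looked at outside the naming rule, gave a partial check of the strain. They cannot show which promoter drove RAP1 in the control, which the headers name WT. LEU2 and MET17 (also called MET15) were listed at 0 in the control and in all 3 doxycycline groups of the authors' deposited tables. HIS3, also mutant per the labels, stood at 267 FPKM in the control of the authors' deposited table for 0.01 µg/mL and was not called (log2 fold changes -0.34, -0.30 and -0.47). URA3, where the labels place the activator, stood at 174 FPKM there and fell at all 3 doses (-0.59, -0.65 and -1.16) in the authors' deposited tables.

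**Figure D1:**
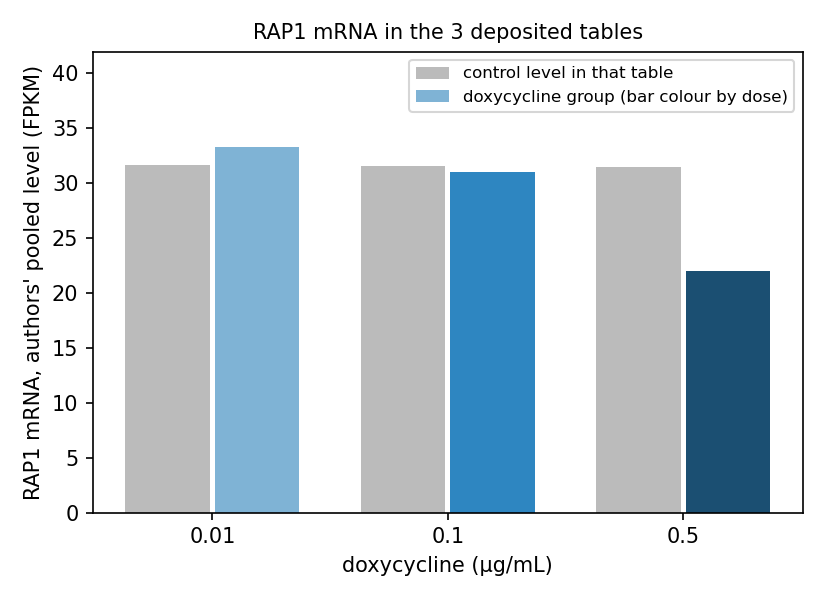
RAP1 mRNA level (FPKM, the authors' pooled level of 3 samples) in the control (grey) and in the doxycycline group (blue) of each of the 3 deposited tables. The bar at 0.5 µg/mL, 22.0 FPKM, lies below its control bar of 31.5 FPKM, while the groups labelled 0.01 and 0.1 µg/mL lie at 33.3 and 31.0 FPKM.

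At 0.01 µg/mL, genes of ribosome production fell and genes of protein folding and stress protection rose. Of 137 ribosomal protein genes, 113 fell and 0 rose, with a median log2 fold change of -0.83 (Fisher's exact adjusted p = 1.4e-68 for the share that fell). Of 25 heat-shock chaperone genes, 22 rose and 0 fell, with a median of 1.86 (exact adjusted p = 1.1e-19 for the share that rose). Over the genome 442 genes rose and 779 fell among 5049 tested.

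The largest rises of the named genes were in protein quality control. In the authors' deposited table for 0.01 µg/mL, BTN2 (YGR142W, chromosome VII), a sorting factor for misfolded proteins, went from 31.0 to 676 FPKM, 21.8-fold (q = 0.000608, the smallest value in that table). The disaggregase gene HSP104 rose 12.9-fold, the Hsp90 gene HSP82 12.8-fold, the small heat-shock protein gene HSP42 14.1-fold and the mitochondrial chaperone gene HSP78 11.7-fold in the authors' deposited table. The Hsp70 genes SSA4 and SSA1 rose 7.36-fold and 7.66-fold and the Hsp110 gene SSE2 6.57-fold in the same authors' deposited table, where SSA1 has a near-identical copy, SSA2. HSP30, which encodes a stress-induced plasma membrane protein, rose 9.09-fold in the authors' deposited table. Of 35 genes of the general stress response, 28 rose and 1, RCK1, fell (median 1.54, exact adjusted p = 9.49e-23 for the share that rose). Its members include TSL1, a subunit of trehalose synthase, with a log2 fold change of 2.85, the phosphoglucomutase gene PGM2 with 2.68 and SOL4 with 2.53 in the authors' deposited table. Of 33 proteasome genes, 3 rose (RPN4, RPN1 and UMP1) and 0 fell, and the list median of 0.38 lay above all 10000 matched random lists (adjusted permutation p = 0.000664, the smallest possible), although the share that rose did not pass Fisher's exact test (exact adjusted p = 0.886).

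Among the genes that fell, RPL29 (YFR032C-A) had the largest change of the ribosomal protein genes, from 5200 to 1601 FPKM in the authors' deposited table (log2 fold change -1.70, q = 0.000608). RPL16A, RPS21B and RPL21B had log2 fold changes of -1.31, -1.30 and -1.30 there, in the authors' deposited table. Of 60 ribosome assembly and rRNA processing genes, 46 fell (median -0.57, exact adjusted p = 1.08e-24), among them the helicase genes DHR2 and DBP2 and the nucleolin-like gene NSR1, at -1.23, -1.07 and -1.22 in the authors' deposited table. Of 22 genes for RNA polymerase I and III subunits and their factors, 14 fell (median -0.48, exact adjusted p = 3.13e-06). Of 22 translation factor genes 0 were called, at a median of -0.29.

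Biosynthetic genes fell as well. Of 51 amino acid biosynthesis genes, 32 fell and 0 rose (median -0.60, exact adjusted p = 1.91e-13). The arginine genes ARG3, ARG1 and ARG4 had log2 fold changes of -2.26, -1.95 and -1.54 in the authors' deposited table, and MET6, the methionine synthase gene, -1.92. Of 16 purine synthesis genes 11 fell (median -0.60, exact adjusted p = 1.64e-05), with ADE17 and SHM2 both at -1.23 in the authors' deposited table. The other large falls in the authors' deposited table were SPG4 (-2.05), the mitochondrial pyruvate carrier gene MPC3 (-1.92), the adenine deaminase gene AAH1 (-1.71) and the acetaldehyde dehydrogenase gene ALD6 (-1.50). Of 17 haploid-specific genes, which include HO and genes of the mating pathway, 10 fell (median -0.53, exact adjusted p = 0.000266), among them HO at -1.64, AGA1 at -0.95, FUS1 at -0.91 and FUS2 at -0.80 in the authors' deposited table.

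Glycolytic genes, which are textbook Rap1 targets, did not fall: of 19, 3 rose (GLK1, HXK1 and TDH1) and 0 fell. Their median was 0.29, while random lists of like level had a median of -0.16 and all genes one of -0.08. The difference from random lists passed (adjusted permutation p = 0.00213), and the share that rose did not pass Fisher's exact test (exact adjusted p = 0.396). Abundant members were not called, such as TDH3 at 0.45 (q = 0.588), which has a near-identical copy, and CDC19 at 0.15 (q = 0.863) in the authors' deposited table. Genes of the TCA cycle and respiration rose in 12 and fell in 1 of 47 cases (median 0.19, exact adjusted p = 0.00229 for rises), with CYC7 and CIT1 at 2.24 and 1.26 in the authors' deposited table. With a minimum change of 2-fold, the counts over the genome were 117 higher and 97 lower, and 2-fold counted from the median of all genes gave 133 and 67, so that the share of rises depends on the minimum change used.

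At 0.1 µg/mL ribosome genes fell and chaperone genes rose, as at 0.01 µg/mL, and most proteasome genes rose. Of 137 ribosomal protein genes, 124 fell and 0 rose (median -0.97, exact adjusted p = 3.66e-70), and 56 of 60 ribosome assembly genes fell (median -0.75, exact adjusted p = 6.26e-33). Of 25 chaperone genes 24 rose (median 2.30, exact adjusted p = 2.04e-16), and of 33 proteasome genes 28 rose and 0 fell (median 0.63, exact adjusted p = 6.89e-16). In all, 888 genes rose and 1031 fell among 5054 tested.

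In the authors' deposited table for 0.1 µg/mL, BTN2 rose 30.5-fold, HSP82 20.7-fold, HSP104 20.6-fold, HSP42 19.4-fold and HSP78 17.7-fold (each q = 0.000329, the smallest value in that table). HSP30, SSE2, SSA1 and SSA2 rose 14.6-fold, 10.1-fold, 11.2-fold and 9.05-fold in the authors' deposited table. Of the 35 general stress genes 29 rose and RCK1 fell (median 1.55, exact adjusted p = 6.89e-16), with TSL1 at a log2 fold change of 3.40 and the nicotinamidase gene PNC1 at 2.84 in the authors' deposited table. Among proteasome genes, RPN4, which encodes the transcription factor of the proteasome genes, went from 125 to 356 FPKM (log2 fold change 1.51), and the base subunit gene RPN1 had 0.97, in the authors' deposited table.

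The largest fall of the named genes in the authors' deposited table for 0.1 µg/mL was that of MET6, from 194 to 22.6 FPKM (log2 fold change -3.10), followed by ARG3 (-2.79), HO (-2.60), ARG1 (-2.52) and MPC3 (-2.48). ADE17, RCK1, RPL29, ALD6 and the uridine permease gene FUI1 followed, at -2.37, -2.35, -2.33, -2.31 and -2.15 in the authors' deposited table. Of 51 amino acid genes 38 fell (median -0.68, exact adjusted p = 1.31e-15), of 16 purine genes 12 (median -0.87, exact adjusted p = 2.71e-05) and of 22 polymerase I and III genes 15 (median -0.59, exact adjusted p = 1.24e-05). Haploid-specific genes fell in 10 of 17 cases (median -0.63, exact adjusted p = 0.00235). Of 19 glycolytic genes 6 rose and 0 fell (median 0.43, adjusted permutation p = 0.00881 against random lists and 0.242 by Fisher's exact test), with GLK1 at 2.13 and PDC1 at 0.92 in the authors' deposited table. TCA cycle and respiratory genes rose in 14 and fell in 2 of 47 cases (rises, median 0.19, exact adjusted p = 0.0786 by Fisher's exact test and 0.0186 against random lists), and 2 of 22 translation factor genes fell (YEF3 and TEF4). With a minimum change of 2-fold, 214 genes rose and 226 fell at 0.1 µg/mL.

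At 0.5 µg/mL, where RAP1 mRNA was called lower, many more genes fell than rose, and the distribution of all genes moved down. Of 5047 tested genes 378 rose and 1962 fell, and the median log2 fold change was -0.30, or -19.0%. FPKM are relative levels, and their sum over all genes was also lower, at 1669270 against 1944490 in the control. Whether the shift is one of scaling is left open below. Of 137 ribosomal protein genes 126 fell and 0 rose, at a median of -1.09, which was -0.78 relative to all genes (exact adjusted p = 3.2e-38 for the share that fell). Ribosome assembly genes fell in 59 of 60 cases (median -1.04, or -0.74 relative to all genes, exact adjusted p = 2.78e-22), and all 22 genes of RNA polymerase I and III fell (median -0.81, or -0.50 relative to all genes, exact adjusted p = 8.12e-09).

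Chaperone and stress genes still rose at 0.5 µg/mL. Of 25 chaperone genes 23 rose (median 1.43, exact adjusted p = 4.77e-23) and of 35 general stress genes 28 rose and RCK1 fell (median 1.07, exact adjusted p = 1.51e-24). In the authors' deposited table for 0.5 µg/mL, HSP104 rose 12.2-fold, HSP82 12.1-fold, BTN2 10.2-fold, HSP42 10.1-fold and HSP78 8.66-fold (each q = 0.000273, the smallest value in that table). HSP30, SSA1, TSL1, SSA2 and the thiamine synthesis gene THI4 rose 8.60-fold, 7.19-fold, 6.50-fold, 5.77-fold and 6.44-fold in the authors' deposited table. Proteasome genes rose in 7 of 33 cases (median 0.34, or 0.64 relative to all genes, exact adjusted p = 0.0297), with RPN4 at 0.96 and UMP1 at 0.77 in the authors' deposited table.

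MET6 had the largest fall of the named genes in the authors' deposited table for 0.5 µg/mL, from 193 to 19.2 FPKM (log2 fold change -3.34), followed by HO (-2.96), ARG3 (-2.86), MPC3 (-2.73) and ARG1 (-2.70). BNA1 of NAD synthesis, RPL29, ARG4, the sulfite pump gene SSU1 and the daughter-cell gene DSE1 had log2 fold changes of -2.60, -2.58, -2.54, -2.50 and -2.46 in the authors' deposited table. Of 51 amino acid genes 45 fell (median -0.99, or -0.68 relative to all genes, exact adjusted p = 3.14e-12), and of 16 purine genes 13 (median -1.15, or -0.85 relative to all genes, exact adjusted p = 0.00404). Haploid-specific genes fell in 14 of 17 cases (median -0.87, exact adjusted p = 0.00229), and 6 of 7 genes specific to MATa cells fell (median -0.90, exact adjusted p = 0.0464 by Fisher's exact test and 0.111 against random lists), among them the pheromone protease gene BAR1 at -1.52 and ASG7 at -1.35 in the authors' deposited table. Of 23 ergosterol synthesis genes 15 fell (median -0.52, exact adjusted p = 0.0464 by Fisher's exact test and 0.126 against random lists), with ERG7 at -1.05 in the authors' deposited table. Glycolytic genes kept a positive median of 0.20, or 0.50 relative to all genes (adjusted permutation p = 0.0127 against random lists), with 3 of 19 higher and 0 lower (exact adjusted p = 0.303 for rises and 0.000736 for fewer falls than among other genes).

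With a minimum change of 2-fold, the share of rises at this dose depends on the reference. Counted as at least 2-fold from 1, 125 genes rose and 509 fell (19.7% rises), and counted as at least 2-fold from the median of all genes, 214 rose and 205 fell (51.1% rises). Without a minimum change 16.2% of the calls were rises. Reading these calls from the median could not alter that share. The smallest absolute log2 fold change called, 0.39, exceeded the size of the shift (-0.30), and the calls themselves were not made anew.

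**Figure D2:**
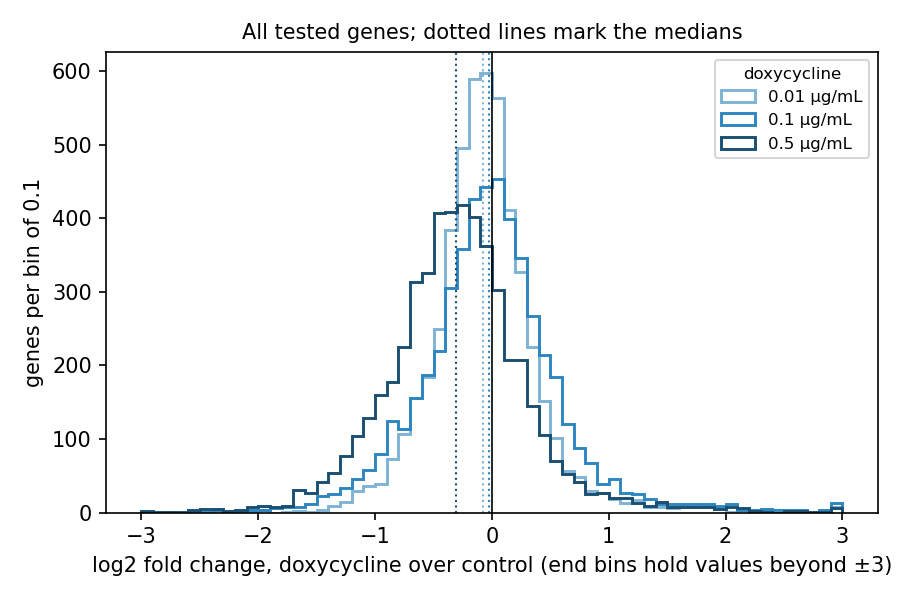
Distribution of log2 fold changes (x axis) over all tested genes (y axis, genes per bin of 0.1) at 0.01, 0.1 and 0.5 µg/mL doxycycline, with dotted lines at the medians. The medians lie at -0.08, -0.03 and -0.30.

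Regulators and silencing factors were examined by dose. SIR2, the histone deacetylase of silent chromatin, fell at all 3 doses, with log2 fold changes of -0.96, -1.46 and -1.69 in the authors' deposited tables. The general regulatory factor genes ABF1 (-0.61, -0.87 and -1.29) and TBF1 (-0.72, -0.88 and -1.23) also fell at all 3 in the authors' deposited tables. SIR3 was at 0.11, 0.24 and -0.08 and RIF2 at 0.11, 0.31 and 0.02, with no call, in the authors' deposited tables. Of the 17 telomere and silencing genes, 4, 5 and 8 fell with rising dose and 0 rose, and no Fisher's exact test passed (exact adjusted p = 0.502, 0.562 and 0.806). Among 12 regulators of ribosomal protein and glycolytic genes, FHL1 fell at all 3 doses (-0.41, -0.54 and -0.77) and TOD6 too (-0.49, -0.75 and -1.08) in the authors' deposited tables. GCR1, an activator of glycolytic genes, rose at 0.01 and 0.1 µg/mL (0.44 and 0.65) and was not called at 0.5 µg/mL (0.36, q = 0.111) in the authors' deposited tables. That list fell in 2, 3 and 7 cases with 1, 1 and 0 rises, and passed no Fisher's exact test (exact adjusted p = 1, 0.863 and 0.397 for falls).

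Genes of the silent mating loci and of alpha cells, and genes near chromosome ends, went both ways. Of 10 genes of the silent mating loci and of alpha cells, 0, 2 and 1 rose and 1 fell at each dose, and no list test passed. HMRA1, whose sequence is shared with the active mating locus of MATa cells, was at 0.29 (q = 0.19), 0.48 (q = 0.00974) and 0.31 (q = 0.147) in the authors' deposited tables. The gene that fell was MF(ALPHA)1, the alpha-factor gene, at -1.03, -1.31 and -1.74 in the authors' deposited tables. Among 147 genes within 20 kb of a chromosome end, 14, 45 and 18 rose (exact adjusted p = 0.886, 0.000489 and 0.0823) and 14, 14 and 30 fell, fewer than among other genes at 0.1 and 0.5 µg/mL (exact adjusted p = 0.102, 0.00229 and 1.3e-05). Their medians were 0.02, 0.16 and -0.08 (adjusted permutation p = 0.0449, 0.000664 and 0.000664 against random lists), and relative to all genes the median at 0.5 µg/mL turned positive, at 0.23. The difference at 0.01 µg/mL no longer passed among members at 10 FPKM or more (adjusted permutation p = 0.113) or within 10 kb of an end (adjusted permutation p = 0.0638), and without families that have near-identical copies no dose passed (adjusted permutation p = 0.167, 0.0704 and 0.0802). The seripauperin (PAU) genes, of which 19 of 24 are among those 147, rose in 2, 9 and 6 cases (exact adjusted p = 1, 0.064 and 0.0234) and fell in 3, 3 and 1 (exact adjusted p = 1, 0.621 and 0.000851, the last for fewer falls than among other genes), with medians of -0.01, 0.34 and 0.30 (adjusted permutation p = 0.674, 0.00654 and 0.000664). Among PAU genes at 10 FPKM or more the median at 0.1 µg/mL was -0.05 (adjusted permutation p = 0.862), so the positive median at that dose depends on members below that level. PAU15 was at 1.03, 1.98 and 2.12 and PAU5 at 0.90, 1.27 and 1.37 in the authors' deposited tables; PAU15 and several other members have near-identical copies. The 11 COS genes had medians of 0.29, 0.40 and 0.19 (adjusted permutation p = 0.0116, 0.0263 and 0.00906), with 1, 6 and 0 rises (exact adjusted p = 1, 0.0208 and 1) and 1, 1 and 2 falls.

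The remaining lists gave mixed or small changes. Sulfur metabolism genes fell in 7, 8 and 13 and rose in 0, 1 and 0 of 20 cases (medians -0.28, -0.23 and -0.50, adjusted permutation p = 0.024, 0.115 and 0.18 against random lists), with SAM1 at -1.62 and SAM2 at -1.58 at 0.5 µg/mL in the authors' deposited table. Mitochondrial ribosomal protein genes fell in 6, 4 and 22 of 65 cases and rose in 0, with medians of -0.20, -0.12 and -0.31, the last at the median of all genes (adjusted permutation p = 0.0501, 0.182 and 0.727). The first lies at the threshold and passed with log2 of FPKM + 1 (adjusted permutation p = 0.0448). Their rises were fewer than among other genes at each dose (exact adjusted p = 0.0208, 2.89e-05 and 0.0421), as were their falls at 0.1 µg/mL (exact adjusted p = 0.0105). Cell wall genes went both ways, with 8 of 23 rising at each dose (exact adjusted p = 0.00221, 0.102 and 0.000789) and 4, 5 and 7 falling, and no median passed against random lists (adjusted permutation p = 0.108, 0.125 and 0.459). The MAP kinase gene SLT2 was at 1.28, 1.86 and 1.49 and TIR1 at -1.01, -1.64 and -1.62 in the authors' deposited tables. Of 16 DNA damage genes 5, 6 and 4 rose (exact adjusted p = 0.0297, 0.102 and 0.067), led by PHR1 at 1.14, 1.45 and 0.99 and MAG1 at 0.86, 1.24 and 0.96 in the authors' deposited tables, while 2, 3 and 5 fell and no median passed (adjusted permutation p = 0.0642, 0.124 and 0.169). Iron regulon genes rose in 4, 9 and 5 of 25 cases (exact adjusted p = 0.435, 0.071 and 0.0804) and fell in 1, 2 and 2 (exact adjusted p = 0.298, 0.269 and 0.00316, the last for fewer falls than among other genes). Their medians were 0.06, 0.24 and -0.05 (adjusted permutation p = 0.129, 0.0352 and 0.0642). Drug efflux and oxidative stress genes went both ways: 4, 6 and 5 of 21 rose (exact adjusted p = 0.207, 0.407 and 0.0483) and 2, 1 and 7 fell, so that at 0.5 µg/mL more fell than rose (median -0.08), and no median passed against random lists (adjusted permutation p = 0.545, 0.545 and 0.134). The peroxiredoxin gene AHP1 led these rises at 1.10, 1.70 and 1.42 in the authors' deposited tables. Phosphate regulon genes fell in 3, 4 and 9 and rose in 1, 2 and 1 of 16 cases, hexose transporter genes rose in 3, 6 and 3 and fell in 1, 1 and 7 of 18, and sporulation genes fell in 4, 3 and 8 and rose in 1, 4 and 2 of 22, with no Fisher's exact test passed. Against random lists the medians at 0.01 µg/mL passed for phosphate regulon genes (-0.34, adjusted permutation p = 0.0164) and hexose transporter genes (0.23, adjusted permutation p = 0.0133), and no median of these 3 lists passed at the higher doses. Histone genes rose in 0, 2 and 0 and fell in 0, 0 and 2 of 10 cases. Translation factor genes fell in 10 of 22 cases at 0.5 µg/mL (exact adjusted p = 0.708), TCA cycle and respiratory genes rose in 5 and fell in 4 of 47 there, fewer falls than among other genes (exact adjusted p = 0.576 for rises and 3.63e-05 for falls; median 0.03, or 0.33 relative to all genes, adjusted permutation p = 0.00654), MATa-specific genes fell in 4 of 7 at 0.01 and 0.1 µg/mL (exact adjusted p = 0.04 and 0.0807 by Fisher's exact test and 0.169 and 0.185 against random lists) and ergosterol genes fell in 5 and 6 and rose in 0 and 2 of 23 (falls, exact adjusted p = 0.576 and 0.619).

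**Figure D3:**
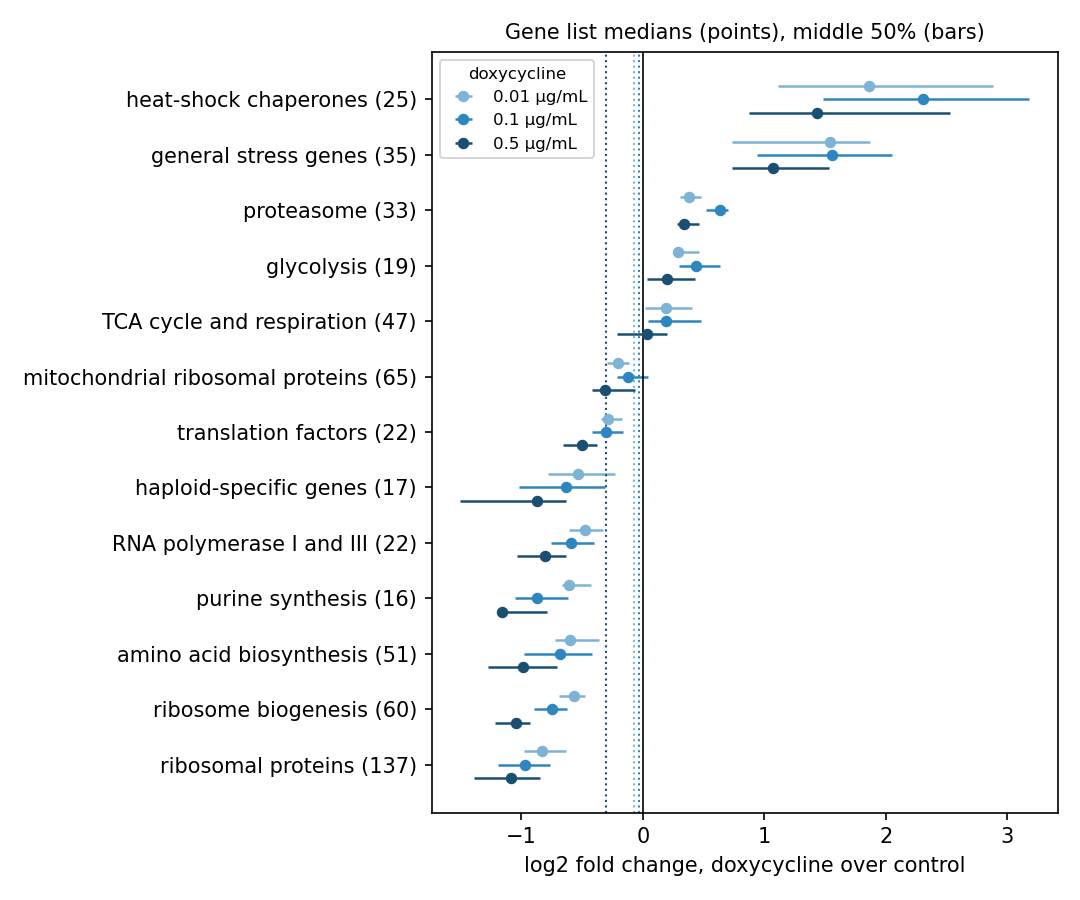
Median log2 fold change (points) and middle 50% of members (bars) of 13 gene lists at 0.01, 0.1 and 0.5 µg/mL doxycycline, with the number of tested genes in parentheses and dotted lines at the medians of all genes. Ribosomal protein genes lie at -0.83, -0.97 and -1.09 and heat-shock chaperone genes at 1.86, 2.30 and 1.43.

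The changes at the 3 doses were alike across genes. Of 5041 genes tested at every dose, 313 rose and 747 fell at all 3, and 8 of the genes with the 10 largest rises were shared by the 3 doses: BTN2, HSP104, HSP30, HSP42, HSP78, HSP82, SSA1 and TSL1. Among the 10 largest falls 6 were shared, namely ARG1, ARG3, HO, MET6, MPC3 and RPL29. At 0.5 µg/mL 921 genes fell that were not called at the lower doses, at a median of -0.56, or -0.26 relative to all genes, and 390 genes rose at 0.1 µg/mL alone. Whether these differ between doses was not tested, because the tables were scaled separately. The gene BSC1, named outside the rule, was the only one called in opposite directions, at 0.83 at 0.01 and -0.88 at 0.5 µg/mL in the authors' deposited tables.

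Pearson correlations of log2 fold changes across genes, which are not independent replicates, were 0.967 between 0.01 and 0.1, 0.957 between 0.1 and 0.5 and 0.912 between 0.01 and 0.5 µg/mL (Spearman 0.964, 0.946 and 0.906). Unchanged groups against shared controls gave 0.501, 0.499 and 0.499 in simulation. These values, and the simulated overlaps below, follow from giving every group the same spread. A control that varied more than the doxycycline groups would raise them. The covariances were 0.293, 0.369 and 0.272 against simulated values of 0.118, 0.117 and 0.117. Between 0.01 and 0.1 µg/mL 437 rises and 751 falls were shared, against 77.9 and 159 for independent lists and 216 and 369 in the simulation. Between 0.1 and 0.5 µg/mL 374 rises and 1017 falls were shared, against 66.6 and 401 for independent lists and 189 and 696 in the simulation. Between 0.01 and 0.5 µg/mL 313 rises and 770 falls were shared, against 33.1 and 303 for independent lists and 122 and 547 in the simulation. The simulated covariances, the most that shared controls give if all groups vary alike, were exceeded by 0.175, 0.251 and 0.155. The 3 control samples could not be split to check this.

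Within lists, 117 of 137 ribosomal protein genes had fold changes that fell from 0.01 through 0.1 to 0.5 µg/mL. Equal odds for each order would give 16.7%, but this ignores the shift of all genes at 0.5 µg/mL and that members change together. Relative to the median of all genes in each table, 9 of 137 had that order. For ribosome assembly genes the counts were 57 of 60 as deposited and 36 of 60 relative to all genes. Chaperone genes were highest at 0.1 µg/mL in 24 of 25 cases as deposited and in 22 of 25 relative to all genes, and proteasome genes in 33 of 33 and 15 of 33.

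The last comparison asked whether ribosomal protein genes with a Rap1 consensus upstream fell more than those without. A match to ACACCCRYACAYM with at most 1 mismatch lay within 600 bp upstream of 38 of the 137 genes. Of these 38, 36 fell at 0.01, 37 at 0.1 and 37 at 0.5 µg/mL, and of the 99 genes without a match 77, 87 and 89 fell. The difference of medians, with minus without, was -0.03, -0.05 and -0.05 (permutation test, two-sided, p = 0.75, 0.489 and 0.562; adjusted p = 0.75 at each dose), so no difference of medians was detected. The share that fell was higher with the motif at each dose, without passing Fisher's exact test (exact adjusted p = 0.0677, 0.167 and 0.29 over 3 doses), which was added after the data were seen. With at most 2 mismatches, 77, 84 and 83 of 86 genes with a match fell against 36, 40 and 43 of 51 without, and this difference passed (exact adjusted p = 0.014, 0.00106 and 0.0192), while the medians differed by -0.03, -0.07 and -0.09 (adjusted permutation p = 0.643, 0.407 and 0.407). Among genes at or below the median control level neither number of mismatches gave a passing difference in the share that fell (smallest exact adjusted p = 0.167). Nearly all genes of this smaller set fell, such as 42 of 42 with and 24 of 27 without a match at 2 mismatches and 0.1 µg/mL. It therefore cannot show that the difference goes away with level. The medians there differed by -0.14, -0.16 and -0.19 at 2 mismatches (adjusted permutation p = 0.247, 0.247 and 0.384) and by -0.01, -0.05 and 0.04 at 1. Whether a difference passed thus depended on the measure and the setting. Among all genes, the 176 with a match upstream fell in 63, 71 and 96 cases and rose in 14, 18 and 14 (falls, exact adjusted p = 1.39e-10, 7.49e-09 and 0.000108), and the 38 ribosomal protein genes are among them. Without ribosomal protein genes, 27, 34 and 59 of 138 fell (19.6%, 24.6% and 42.8%, against 13.4%, 18.3% and 37.2% of other genes), which did not pass Fisher's exact test (exact adjusted p = 0.111, 0.111 and 0.211 over 3 doses), a comparison added after the data were seen. Ribosomal protein genes not called at any dose were 10: RPL3, RPL4A, RPL4B, RPL10, RPL39, RPP1A, RPP2B, RPS21A, RPS22B and RPS28A. Their median control level was 4495 FPKM, against 1899 FPKM for the 113 called at all 3 doses. RPL39 stood at 0.08, 0.08 and 0.05 and RPP1A at -0.01, -0.12 and 0.01 in the authors' deposited tables.

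**Figure D4:**
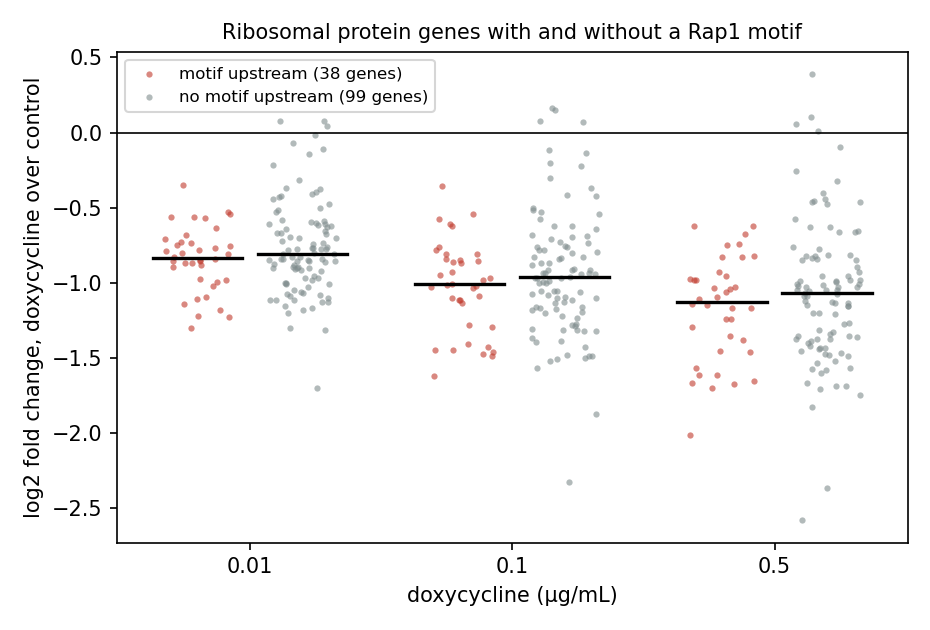
Log2 fold change (y axis) of the 137 ribosomal protein genes at 0.01, 0.1 and 0.5 µg/mL doxycycline (x axis), split by a Rap1 motif upstream (red, 38 genes) or none (grey, 99 genes), with black lines at the medians. The differences of the medians are -0.03, -0.05 and -0.05, and the points above 0 are genes without the motif.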

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

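The alternatives below were set before the data were examined, except 2-fold from the median of all genes, the 2 gene removals, the motif settings without near-identical copies and at or below the median control level, the tests of the share of ribosomal protein genes that fell with the motif, and the motif genes without ribosomal proteins, which were chosen after the data were seen. No paired analysis was possible because the tables hold 1 pooled level per group. For the same reason alternatives that need counts or values of single samples were not run, nor was a new adjustment of p-values. The medians of ribosomal proteins, ribosome assembly, chaperones, general stress, glycolysis and amino acid biosynthesis kept their direction and their side of the threshold at all 3 doses under both centrings, log2 of FPKM + 1 and members at 10 FPKM or more, and so did the ribosomal proteins with RPP1. Centring subtracts the same value from members and random lists, so the p-value could not change and only the direction was open. All ribosomal protein genes lay far above 10 FPKM, so that minimum removed none of them.

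Over all 31 lists and 3 doses, 354 of 384 alternative medians kept both, 5 lost a call (genes near chromosome ends, 3 at 0.01 and 1 each at 0.1 and 0.5 µg/mL) and 2 gained one (mitochondrial ribosomal proteins at 0.01 and the iron regulon at 0.5 µg/mL), 20 uncalled medians changed sign and 3 called medians reversed. Of these alternatives, the centred medians could change in direction only, for the reason given above. The PAU median at 0.1 µg/mL turned to -0.046 among members at 10 FPKM or more. The median of genes near chromosome ends at 0.5 µg/mL turned to 0.23 and 0.20 when centred on all genes and on genes outside 4 lists, which follows from the shift of -0.30 subtracted. At 0.01 µg/mL a minimum of 2-fold left 117 rises and 97 falls, 2-fold from the median of all genes 133 and 67, and a q below 0.01 left 488 falls. At 0.1 µg/mL the 2-fold counts were 214 and 226, and from the median 220 and 209. At 0.5 µg/mL they were 125 and 509, and from the median 214 and 205. These counts fall by the construction of the stricter minimum; the turn from mostly falls to about as many rises at 0.5 µg/mL follows from the shift. Rises were 36.2% of all calls at 0.01 µg/mL, 54.7% with 2-fold and 66.5% with 2-fold from the median. The uncalled motif difference at 0.5 µg/mL and 1 mismatch moved to 0.040 among genes at or below the median control level. With 2 mismatches it moved the other way, from -0.091 to -0.193, and the cause was not tested. The depth of the libraries is unknown, so its limits cannot be given.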

Other observations

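Of the tests below, the split by control level, by coding length and GC content, by near-identical copies, and the comparison of medians with and without the motif among all ribosomal protein genes were set before their results were seen, and the tests of RAP1 level, of doxycycline, of genes called at no dose, of separate scaling, of the share called with the motif and of the motif at or below the median control level were chosen afterwards. The bounds of the motif comparison were changed once its value was known and then set back, and the rules for reading it beside the shares, for reading the comparison at or below the median level, and for asking that fewer sites hold at both numbers of mismatches were added after the values were seen. So was the reading of the genes called at no dose, whose difference passed the bound of 0.5 written against that explanation and is nevertheless left open.

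Of 16, 16 and 15 genes of the mitochondrial genome tested at 0.01, 0.1 and 0.5 µg/mL, 2, 5 and 6 rose and 0 fell, and the others were not called. The median log2 fold changes were 0.54, 1.24 and 1.23, and 4, 2 and 1 members lay below 0, such as RPM1 at -0.56, AI1 at -0.30 and VAR1 at -0.25 at 0.01 µg/mL in the authors' deposited table. The group was picked after its values were seen, so no test is given. The ATP synthase gene OLI1 went from 69.9 FPKM to 169, 276 and 314 FPKM in the authors' deposited tables, and the large rRNA gene, 21S_RRNA, had log2 fold changes of 0.58, 1.17 and 1.25. Most other members lay near 1 FPKM, with a median control level of 1.12 FPKM against 82.5 FPKM for all genes in the first table. The libraries were made from polyA RNA, and how these transcripts entered them was not tested.

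The median of all genes at 0.5 µg/mL was -0.30. A single scaling factor of that table would move genes of every level alike; in 4220 genes outside the lists by symbol, the 0.5 minus 0.1 µg/mL difference had medians between -0.19 and -0.34 over deciles of control level, a range of 0.148 (95% bootstrap interval 0.132 to 0.165), between the bounds set for and against. A length or GC bias was not excluded either, since the median was least negative, at -0.172, among the shortest coding lengths. RAP1 mRNA was called lower at this dose alone (-0.519), between the lower and upper quartiles of all genes there (-0.64 and 0.02). Its fall was thus not set apart from the shift itself. With no group that separates dose from RAP1 level, the part of RAP1 in the shift cannot be told apart. The sum of level times coding length over genes was lower at this dose too (log2 ratio -0.234, against -0.050 at 0.01 and 0.022 at 0.1 µg/mL). By itself this sum does not tell these explanations apart. All of them stay open.

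Ribosomal protein genes fell at 0.01 µg/mL (median -0.828), where RAP1 mRNA did not; without doxycycline-treated cells that carry the native RAP1 promoter, an effect of doxycycline cannot be told apart from one of Rap1. A response that lowers these genes whatever their upstream sites stays open. The medians with and without the motif differed by -0.0279 (95% bootstrap interval -0.0998 to 0.0671, two-sided permutation p = 0.75). Most ribosomal protein genes are known Rap1 targets, so genes without a match can be bound too and alike medians do not decide the question. Against such a response, more of the genes with a motif at 2 mismatches fell at 0.01 µg/mL (Fisher's exact adjusted p = 0.014), a test added after the data were seen. At the planned limit of 1 mismatch the share that fell did not pass (Fisher's exact adjusted p = 0.0677). A sequence match is also an imperfect stand-in for Rap1 binding. Among genes at or below the median control level the difference of medians at 1 mismatch was -0.0119. It decides nothing about abundance because there was no difference of medians to remove. With 2 mismatches the medians there differed by -0.136. The share that fell was 7.67 percentage points higher with the motif in that set, against 18.95 over all ribosomal protein genes. In the smaller set this did not pass (exact adjusted p = 0.42), which does not settle the part of abundance either. Of the 10 members called at no dose 1 had the motif, against 37 of the 127 others (Fisher's exact p = 0.283). With 2 mismatches allowed 2 had it, against 84 of the others (Fisher's exact p = 0.00567). Fewer sites among them thus hold at 1 setting only and stay open. The comparison largely repeats that of the shares above, because genes called at no dose count as not falling at every dose. Whether these 10 fell like the others and were missed stays open too: their median at 0.5 µg/mL was 0.948 above that of the others, with members from -0.62 to 0.39, but picking genes for lacking a call puts them above the others, so this value excludes nothing.

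Chaperone genes rose less at 0.5 than at 0.1 µg/mL. After each table was centred on its median of all genes, the median difference per gene (0.1 minus 0.5 µg/mL) was 0.465, above 0 in 23 of 25 members, which argues against separate scaling as the whole cause. Without the members that have a near-identical copy it was 0.482, above 0 in 21 of 23, which argues against reads shared between copies. A weaker response at the highest dose may be biological, as a hypothesis found and tested on the same data. The difference between tables could not be tested against the spread between samples, which leaves sampling open.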
